A study of Populus davidiana with 6 samples.

How the data were processed

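Poly(A) RNA from leaves of Populus davidiana Palgong1 was made into libraries with a TruSeq RNA kit, which does not mark strand, and sequenced as 100 bp read pairs on an Illumina HiSeq, per the labels' protocols. Samples were placed in groups by their labels, 3 control and 3 air-dried. The deposited values are FPKM per transcript, per the file headers. The submitters' processing notes name FastQC, TopHat and Cufflinks; their versions and settings, the genome build and the annotation are not given in the sources used here. All 6 files list the same 112919 transcripts, 45773 marked as known and 67146 as new, so a single transcript set was quantified in every sample. No read counts were used here, and FPKM values run down to far below those of 1 fragment, so the depth per sample is unknown, whole reads were not recovered across loci and no count test was run. There were 11 single-transcript loci of 150 bases, with 3 to 6 values above 1 FPKM per sample. In every sample but control replicate 1 these values were whole multiples of that sample's smallest value, with a tolerance of 0.02. The smallest value counts as a multiple of itself.

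FPKM values of the transcripts of a locus were summed. Summed FPKM per sample over all loci was 343937000 in control replicate 1, 10915500 and 1648880 in control replicates 2 and 3, and 5120940, 7682340 and 7744470 in air-dried replicates 1, 2 and 3. Loci under 300 bases held 42.8% of this sum in control replicate 3 and 75.4% to 93.0% in the other samples. Over loci of 300 bases or more they were 24097700, 1188410, 942883, 1258020, 976112 and 976934 in the same order. Exact zeros made up 11.8% to 17.2% of the transcripts of a sample and can be failed estimates, so a locus at 0 is described only as listed at 0.

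The planned test, fixed before the data were examined, was limma on log2(FPKM + 1) with a mean-dependent variance and no block, over loci with a mean of at least 1 FPKM over the 6 samples (22835 loci). Calls needed a Benjamini-Hochberg adjusted p under 0.05. Fold changes on this scale understate changes of weakly expressed loci. Ratios of mean FPKM are given beside them where stated. Loci with a reference identifier were classed as annotated, taken as annotated models alone, or as extended where the identifier was marked as revised, taken as models with added transcripts. The status of single transcripts was not checked for these classes. Loci with a new identifier were classed as merged (with known transcripts, taken as merged models) or new (no known transcript). The comparisons by class, by chromosome and by neighbourhood and the comparison of transcript shares were chosen after the data were seen. Shares were compared by limma after an arcsine square-root transform, in loci with a mean of at least 5 FPKM and for transcripts with a mean share of 5% to 95%.

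The rule planned for naming genes took the 12 largest rises and falls with a descriptive product name, and 30 gene lists (abscisic acid, heat shock, transcription factor families and others) were to be tested with camera. Both needed gene names. The files give a gene name for 0 transcripts, and no table pairing identifiers with names was used here, so neither the rule nor the lists could be applied, and no gene list was tested. In their place 2 rises and 2 falls are named by identifier, and series of neighbouring loci by position. These were chosen after their values were seen.

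The steps were tested on simulated data. For the fit to loci, these were built from the means and spread of these samples. For the neighbour test, loci were marked as called at random along their real positions. For the shares, a fixed noise was added to the mean shares. It was smaller than the real spread between replicates (median SD 11.3 percentage points in control and 7.18 in air-dried leaves). For the comparison of air-dried with control leaves, over 22834 loci, limma recovered 42% of 100 planted 2-fold changes and 78% of 100 planted 4-fold changes, and called 5 unchanged loci. The neighbour test gave a permutation p of 0.194 without planted pairs and 0.000999 with 40 planted pairs. The test of shares recovered 99.5% of 200 planted shifts with a median of 44.5 percentage points, over 31945 transcripts, and called 0 transcripts without a shift. It recovered 0% of 200 smaller shifts with a median of 10.8 points. As the simulated noise was smaller than the real spread, these recoveries can overstate what the test of shares could detect here.

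Alternatives covered the pseudocount, the filter on low values, the scaling between samples, the variance trend, sample weights, a block for the replicate number, each sample left out in turn, a 2-fold minimum and transcripts in place of loci. Added after the data were seen were: loci under 300 bases left out, with and without control replicate 1; known transcripts only; a term for the 3 libraries with the highest values at 150-base loci; and a minimum of 20 FPKM for the shares. Computation used R 4.3.3 with limma 3.58.1 and the data.table package (1.17.8), and plots used Python 3.11.15 with matplotlib 3.10.9.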

Results

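Leaf RNA was sequenced from Populus davidiana, an aspen, of the cultivar Palgong1, which the labels class as drought sensitive. The plants were grown in sterile culture for about 6 weeks. Air-dried plants were lifted from the medium, rinsed and exposed to open air for about 10 min, and control plants supplied the other group. Each group held 3 samples. Expression was given as FPKM (fragments per kilobase of transcript, scaled to the fragments sequenced) for 112919 transcripts, which belonged to 40537 loci. Read or fragment totals were not given in the sources used here, so the depth of each sample is unknown and no counting intervals are given. Loci of 150 bases with a single transcript numbered 11. In 5 of the 6 samples, their 5 or 6 values above 1 FPKM were whole multiples of the smallest one (tolerance 0.02). Values at such loci can therefore rest on very few fragments. At least 1 FPKM was listed for 21755 to 22461 loci per sample.

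Control replicate 1 stood apart from the other 5 samples. Over the 22835 tested loci, its Pearson correlation with another sample across loci was 0.607 to 0.657, against 0.864 to 0.941 among the others. These are correlations across loci within pairs of samples, and loci are not independent replicates. Values at very short loci accounted for part of this gap. Loci spanning under 300 bases carried 93.0% of all FPKM in control replicate 1, with 192 of them at 10000 FPKM or more, and 42.8% to 89.1% in the other 5 samples. Over loci of 300 bases or more, control replicate 1 still had correlations of 0.860 to 0.889, against 0.926 to 0.980 among the others. The plot of control replicate 1 by locus span shows this departure.

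**Figure D1:**
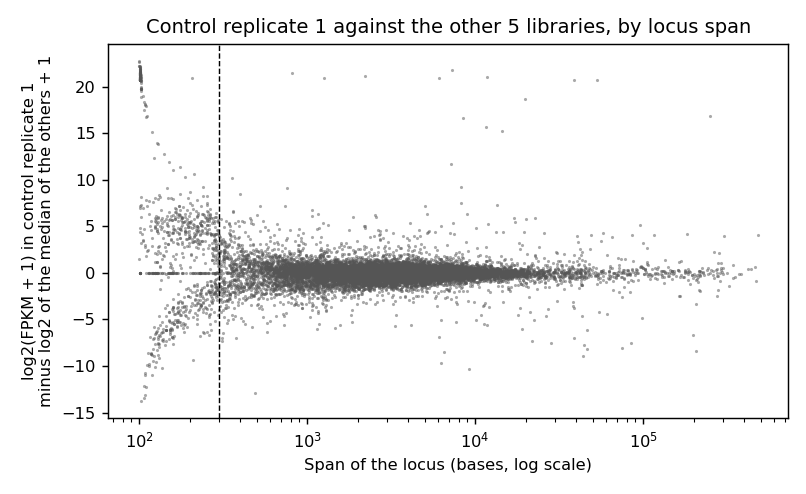
Each point is a tested locus, with its span in bases on a log axis and, on the vertical axis, log2(FPKM + 1) in control replicate 1 minus the log2 of the median FPKM of the other 5 samples plus 1. The dashed line marks 300 bases, under which 872 of the 22835 tested loci lie and where the differences are widest.

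The comparison of air-dried with control leaves asked which transcripts differed in the leaf after whole plants were lifted, rinsed and exposed to open air, a treatment the study used as drought stress; the handling of control plants is not given in the sources used here. More loci rose than fell. In air-dried leaves 951 loci rose, 4.16% of those tested, and 597 fell, 2.61%. The loci that rose had medians of 11.5 FPKM in control leaves and 22.8 FPKM in air-dried leaves. Those that fell had medians of 29.0 FPKM in control and 14.9 FPKM in air-dried leaves. Sorting loci by direction of change itself tends to give such a difference in control level. Most changes were moderate: the median log2 fold change was 0.80 for rises (quartiles 0.57 and 1.17) and -0.75 for falls (quartiles -1.17 and -0.53).

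Large changes occurred in both directions. Among loci of 300 bases or more, 56 rose and 43 fell by at least 4-fold, and 18 rose and 16 fell by at least 8-fold, on the scale of log2(FPKM + 1). In 12 loci the mean went from under 1 FPKM in control leaves to at least 5 FPKM in air-dried leaves, and in 8 it went the opposite way. Abundant transcripts were among those that changed. Of the 1685 loci of 300 bases or more with a mean of at least 100 FPKM in either group, 96 rose and 97 fell, with changes of at least 4-fold in 14 and 10 of them. The first 12 rises by log2 fold change at loci of 300 bases or more had ratios of mean FPKM from 9.45 to 32.0 and lay on 9 chromosomes or other genome sequences. The first 12 falls had ratios from 9.10 to 26.8 and also lay on 9 chromosomes or other genome sequences.

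The files do not pair locus identifiers with gene names, so only 4 loci are named, and these were chosen after their values were seen. Among called loci with an identifier from the reference annotation, they had the largest 2 rises and the largest 2 falls in log2(FPKM + 1). A ranking by ratio of mean FPKM can differ. POPTR_0018s08320, a single-transcript locus on the plus strand of chromosome 18 (9245946 to 9246542), rose 32.0-fold, from 5.22 ± 2.59 to 167 ± 57.4 FPKM (mean ± SD, n = 3 per group; limma log2 fold change 4.80, SE 0.41, adjusted p = 0.00464). POPTR_0009s16050, also with 1 transcript on the plus strand, on chromosome 9 (12284978 to 12286144), rose 15.7-fold, from 7.19 ± 2.84 to 113 ± 7.03 FPKM (limma log2 fold change 3.86, SE 0.26, adjusted p = 0.00257). POPTR_0002s01870.r1, with 5 transcripts on the minus strand of chromosome 2 (997286 to 1003043), went down from 163 ± 6.68 to 6.09 ± 0.72 FPKM, a ratio of 26.8 (limma log2 fold change -4.54, SE 0.09, adjusted p = 0.000237). POPTR_0010s09950.r1, with 3 transcripts on the plus strand of chromosome 10 (10551687 to 10554183), went down from 143 ± 25.3 to 6.26 ± 1.47 FPKM, a ratio of 22.8 (limma log2 fold change -4.31, SE 0.20, adjusted p = 0.000769). Coordinates are those of the deposited tables, whose genome build is not given in the sources used here. With annotated transcripts alone, the call for POPTR_0002s01870.r1 ended (log2 fold change -1.29, limma adjusted p = 0.649, against a range of 0.0000527 to 0.649 over its 19 alternatives), so this call rested on newly assembled transcripts of the same locus. The call for POPTR_0018s08320 ended with the replicate number as a block (log2 fold change 4.80, limma adjusted p = 0.0592).

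**Figure D2:**
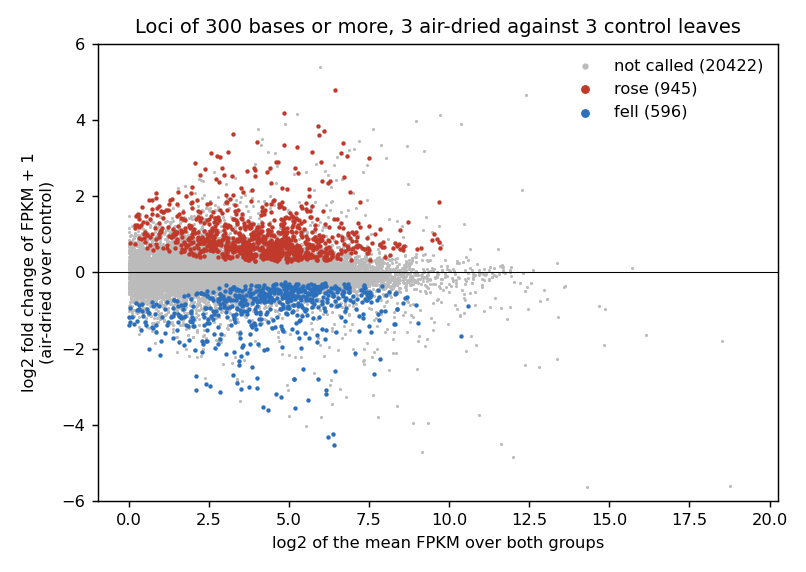
Each point is a tested locus of 300 bases or more, with the log2 of its mean FPKM over both groups on the horizontal axis and the log2 fold change of FPKM + 1, air-dried over control, on the vertical axis. Red points are the 945 loci that rose and blue points the 596 that fell by limma at an adjusted p under 0.05; 10 loci lie outside the axis limits of 6 on either side.

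The test was limma on log2(FPKM + 1) with a mean-dependent variance and Benjamini-Hochberg adjustment, and 1548 of 22835 loci (6.78%) passed an adjusted p of 0.05; 5032 had an unadjusted p under 0.05. In every called locus the 3 air-dried values lay wholly above or wholly below the 3 control values. The calls were made from these same values, so this is not separate evidence for them. Over all tested loci 6934 (30.4%) had no overlap, against 10% by chance. The median log2 fold change over all tested loci was 0.0066. Of the 1548 called loci, 1258 were called in the same direction without control replicate 1, where 1738 loci passed. Leaving out any one of the other samples lowered the count by over 1.5 times, to 632 without control replicate 2, 900 without control replicate 3, and 526, 376 and 388 without air-dried replicates 1, 2 and 3. Nothing in the labels says that samples of a group came from separate plants, so the p-values measure only the spread between these samples, which may be technical.

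The largest fitted changes belonged to very short loci and carry no usable fold. A newly assembled locus of 102 bases on chromosome 8 (6993174 to 6993275) was listed at 0 FPKM in all 3 control samples and at 69855, 13981 and 14554 FPKM in air-dried replicates 1, 2 and 3. The smallest value above 1 FPKM listed at any 102-base locus was 34928, 13981 and 14554 FPKM in the same samples, so in 2 of them this locus stood at the lowest such value. A newly assembled locus of 107 bases on the same chromosome (11040136 to 11040242) was listed at 0 in all 3 air-dried samples. Only 6 rises and 1 fall were called at loci under 300 bases.

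Loci were next compared by how they related to the annotation. Loci classed as annotated both rose and fell more often than expected from their expression. The difference between the excesses was not tested. Of 5133 such loci tested, 361 rose (7.03%) where 197 were expected (95% of draws 174 to 221), and 170 fell (3.31%) where 121 were expected (103 to 140). Loci classed as extended rose less often than expected, with 485 of 14184 (3.42%) against 608 (580 to 636). Wholly new loci, whose median span was 275 bases, were rarely called: 12 of 1334 as rises where 51.8 were expected, and 12 as falls where 35.3 were expected. These ratios, 0.23 for rises and 0.34 for falls, moved by over 1.5 times when 1 library was left out. For rises they were 0.50 and 0.59 without control replicates 2 and 3, and 0.58, 0.40 and 0.40 without air-dried replicates 1, 2 and 3. For falls they were 0.92 without control replicate 3, and 0.61 and 0.21 without air-dried replicates 1 and 3. The plot of shares by locus class shows these values.

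**Figure D3:**
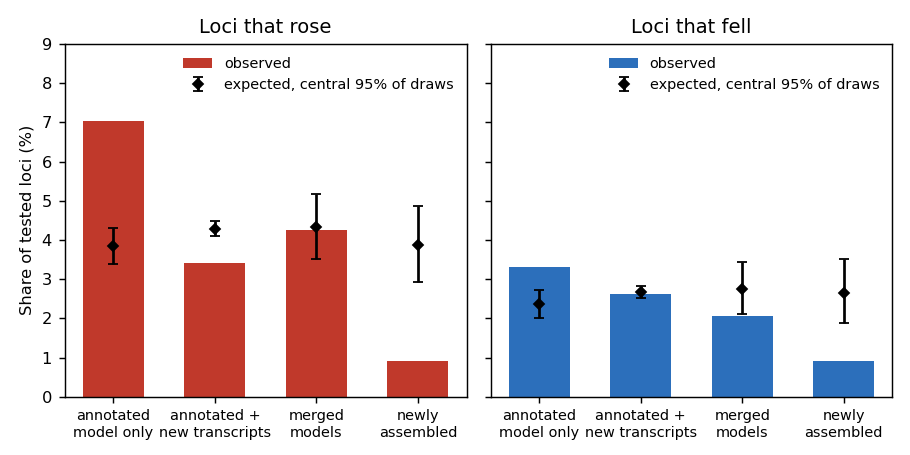
Bars give the percentage of tested loci in each of 4 classes that rose (left) or fell (right). Diamonds give the percentage expected from draws matched on expression, with lines over the central 95% of 100000 draws. Rises among loci classed as annotated reached 7.03%, above the draws.

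Expected numbers came from 100000 draws of the called loci within 10 strata of mean expression, with 2-sided permutation p-values adjusted over 8 tests. Adjusted p was 5.33e-05 for the excess of rises and 6.4e-05 for the excess of falls among annotated models, 5.33e-05 for the deficit of rises among extended loci, and 5.33e-05 and 6.4e-05 for the deficits of rises and falls among new loci; 5.33e-05 corresponds to the smallest p these draws can give. Falls among extended loci (370 against 380 expected, adjusted permutation p = 0.45), rises among merged loci (93 of 2184 against 94.6, adjusted p = 0.915) and falls among merged loci (45 against 60.1, adjusted p = 0.052) did not pass. With p adjusted in the same way within each alternative, falls among new loci no longer passed when loci under 300 bases were left out (0.96 of the expected number, adjusted permutation p = 1), without control replicate 3 (0.92, p = 0.781) and without air-dried replicate 1 (0.61, p = 0.208), and rises among new loci no longer passed without air-dried replicate 1 (0.58, p = 0.0831). Falls among merged loci passed as a deficit under 10 of 19 alternatives, among them loci under 300 bases left out (0.64 of the expected number, adjusted permutation p = 0.000832), without control replicate 1 (0.72, p = 0.0287) and without control replicate 3 (0.58, p = 0.0108), so this result lay close to the threshold. Falls among extended loci passed as a deficit under 5 of 19: quantile normalization (0.85 of the expected number, adjusted permutation p = 8e-05), without control replicate 3 (0.88, p = 0.0042), without air-dried replicate 1 (0.87, p = 0.0364), loci under 300 bases left out (0.94, p = 0.0228) and known transcripts only (0.88, p = 0.0126). Draws were matched on expression only, and the classes also differ in median span, from 275 bases for new loci and 1658 for annotated models to 9191 for merged loci. Transcripts per locus and the spread between samples were not matched either. Whether the classes differ in response or in how readily a change is detected was not tested.

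Changed loci were found on all 19 chromosomes, and neighbouring loci fell together more often than with calls placed at random among tested loci. Some tested and called loci lay on other genome sequences, which the comparison by chromosome left out. The share that rose ran from 2.75% on chromosome 8 to 5.73% on chromosome 3, and the share that fell from 1.89% on chromosome 16 to 3.41% on chromosome 9. Unevenness was not detected by a permutation test over chromosomes (p = 0.124 for rises and 0.360 for falls, adjusted p = 0.248 and 0.360). This does not show that the shares were even. There were 36 pairs of adjacent tested loci that both fell, against 16.0 expected (95% of permutations 9 to 24), and 52 pairs that both rose, against 40.6 (29 to 53).

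Some neighbours formed longer series. Runs of at least 3 adjacent tested loci that changed in 1 direction numbered 8 for rises, with 25 loci, and 3 for falls, with 10 loci. On chromosome 3, from 14928871 to 14946666, 3 loci rose with log2 fold changes of 1.46, 3.01 and 2.12; the middle one went from 39.8 ± 6.44 to 326 ± 22.0 FPKM (n = 3 per group; limma adjusted p = 0.000728). The third locus there went from 0.435 ± 0.095 to 5.32 ± 1.15 FPKM. On chromosome 5, from 16355550 to 16393441, 3 loci rose with log2 fold changes of 1.91, 2.25 and 0.99. The first went from 0.0966 ± 0.127 to 3.19 ± 0.963 FPKM and the next from 0.754 ± 0.549 to 7.04 ± 0.276 FPKM. Their control means lay under the 1 FPKM added before the log. On chromosome 14, from 1914852 to 1949454, 3 loci rose, the first of them from 17.0 ± 1.67 to 47.3 ± 0.45 FPKM (n = 3 per group; limma log2 fold change 1.43, adjusted p = 0.00175). On chromosome 16, from 4427236 to 4439995, 3 loci fell, from 107 ± 14.3 to 30.8 ± 2.10 FPKM, from 132 ± 1.80 to 44.0 ± 1.36 FPKM and from 39.6 ± 1.78 to 23.3 ± 0.54 FPKM. The spans of these 3 loci overlap and lie on alternating strands, and the library kit does not mark strand, so their reads cannot be fully told apart. On chromosome 8, from 3475569 to 3509993, 3 loci on the plus strand fell, the last from 261 ± 27.9 to 97.9 ± 4.12 FPKM (n = 3 per group; limma log2 fold change -1.40, adjusted p = 0.00277). A series of 4 loci fell on chromosome 6, from 11499652 to 11521139, with log2 fold changes between -0.85 and -0.51.

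**Figure D4:**
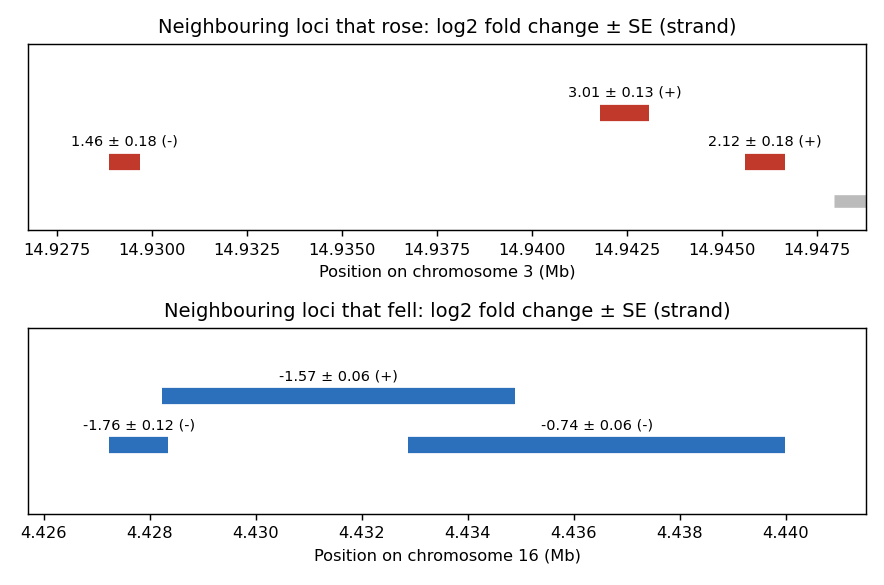
Boxes mark loci by position in Mb on chromosome 3 (top) and chromosome 16 (bottom), with the log2 fold change of each called locus, its SE and its strand; gray boxes are tested loci that were not called. The 3 loci on chromosome 3 rose by 1.46 to 3.01 and the 3 on chromosome 16, whose spans overlap, changed by -1.76 to -0.74.

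The pair counts were compared with 10000 permutations of the calls among the tested loci of each sequence, 1-sided. The permutations were not matched on expression, class or span. The share of falls differed by class, at 3.31% of annotated and 0.90% of new loci, and its effect on the pairs was not tested. Permutation p was 1e-04 for falls, the smallest these permutations can give (adjusted p = 4e-04 over 4 tests), and 0.0408 for rises (adjusted p = 0.0408). With pairs at least 1000 bases apart, 27 pairs fell against 13.3 expected (permutation p = 6e-04, adjusted p = 0.0012) and 45 pairs rose, at the upper end of the 95% range of 24 to 45 (permutation p = 0.0339, adjusted p = 0.0408). The ratio of pairs that fell to those expected, 2.25, was 5.17, 6.40 and 5.55 without air-dried replicates 1, 2 and 3, where fewer loci were called. The ratio for rises, 1.28, passed narrowly. Under 8 of 19 alternatives its unadjusted permutation p was above 0.05 (up to 0.166) at ratios of 1.15 to 1.79; 2 of these left out 1 library, air-dried replicate 1 (1.58, p = 0.0797) or air-dried replicate 3 (1.79, p = 0.0878). Without control replicate 2 or air-dried replicate 2 the ratio for rises was 2.05 and 2.12.

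The make-up of each locus by transcript was also compared. No change in a transcript's share of its locus was detected in air-dried leaves. Of 31655 transcripts in 10993 loci, 0 passed an adjusted p of 0.05 by limma on arcsine-transformed shares, the lowest adjusted p being 0.496, and 1455 (4.60%) had an unadjusted p under 0.05; no other tool was run. The shares varied widely between replicates, with a median SD of 11.3 percentage points in control and 7.18 in air-dried leaves, against a median absolute difference of 7.27 points between groups. In simulated data planted shifts with a median of 10.8 points were recovered in 0% of cases, so shifts of about that size were not detectable by this test. The simulated noise was smaller than the spread of these samples. Larger shifts can therefore also have been missed, and the absence of calls does not exclude them.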

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

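The alternatives without some or all loci under 300 bases, with known transcripts only, with the library term and with a higher minimum for shares were chosen after the data were seen. The count of 1548 called loci (951 rose, 597 fell) stayed within 1.5 times under 11 of 21 alternatives, among them both other pseudocounts, both filters, size factors, quantile normalization and no variance trend. Sample weights raised it to 3371 (2003 rose, 1368 fell), for which the cause was not tested. With a 2-fold minimum it was 523 (321 and 202) by construction. It was 296 (175 and 121) with transcripts in place of loci and 727 (440 and 287) with known transcripts only; the cause was not tested. Leaving out 1 sample gave 376 to 1738 calls (229 to 1122 rises and 147 to 616 falls) with fewer samples in the test: 1738 without control replicate 1, 632 and 900 without control replicates 2 and 3, and 526, 376 and 388 without air-dried replicates 1, 2 and 3. Without loci under 300 bases 1791 loci were called, of which 1527 were among the 1548, and 2000 when control replicate 1 was left out as well. The labels state no pairing of the replicate numbers. Deviations from the group mean in samples with the same number correlated at 0.025, -0.065 and 0.050. Not every sample correlated best with its own number. Control replicate 1 stood apart and can dominate the control deviations, so these correlations cannot settle whether the samples are paired. With the replicate number as a block the count was 281 (167 rises and 114 falls), of which 274 were among the 1548, and POPTR_0018s08320 had a limma adjusted p of 0.0592 (0.000826 to 0.0592 over its 19 alternatives). For the 4 named loci, 74 of 76 values kept direction and call; the other exception was POPTR_0002s01870.r1 with known transcripts only. The excess of rises and of falls among annotated loci, the deficit of rises among extended loci and the excess of adjacent falls (1.58 to 7.22 times the expected number) passed under all 19 alternatives. The excess of adjacent rises stayed above expected under all 19 (1.15 to 3.16 times) but did not pass under 8. New loci stayed below expected under all 18 (0.23 to 0.59 for rises and 0.21 to 0.96 for falls) but did not pass under 2 (rises) and 5 (falls); known transcripts only leaves no new locus to compare. Where the replicate block ended these calls the ratios were 0.36 and 0.44. Falls among merged loci became a deficit under 10 of 19 and falls among extended loci under 5 of 19. Unevenness in the share of rises between chromosomes was detected only with sample weights (adjusted permutation p = 0.0068). The count of transcripts with a changed share was 0 by limma under all 9 alternatives. Tests of gene lists and DESeq2 were not run, as the files gave neither gene names nor counts to use. Depth, which sets the precision of weakly expressed loci, is unknown.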

Other observations

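All tests here were chosen after the results were seen, except the comparison of the locus count with other splits of the samples. The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1548 called loci, as many as only 1 of the 10 splits (itself), and the highest other split gave 25. For transcript shares the real split gave 0, so that all 10 of the 10 splits had to give as many and the comparison says nothing about chance; the highest other split gave 220.

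That other split, control replicates 1 and 2 with air-dried replicate 1 against the remaining 3, crosses the study's groups and points to a structure of the samples. It may reflect a difference between libraries in the length or number of sequenced fragments. At 11 single-transcript loci of 150 bases, the smallest value above 1 FPKM in each library was compared. It was 4776, 46.2 and 79.4 FPKM in these 3 samples and 8.16, 18.3 and 17.6 FPKM in the others. The lowest of the first set (46.2) lay above the highest of the second (18.3). Each minimum was taken over only 3 to 6 values. In control replicate 1 only 33.3% of its 3 values were whole multiples of the smallest. A parting of so few values into these sets can also arise by chance. At 102 bases the same samples were again apart, with 803185, 28712 and 34928 FPKM against 6633, 13981 and 14554 FPKM. At 101 bases control replicate 2 and air-dried replicate 1 lay above the second set (99945 and 121729 against at most 53792 FPKM), but control replicate 1 had the lowest value of all 6, 147.5 FPKM. These values do not tell length from number of fragments. With a term for these 3 libraries 1263 loci were called, and no biological explanation for this split was tested.

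The distance of control replicate 1 from the other 5 libraries may have a technical source, but loci under 300 bases alone do not account for it. Over loci of 300 bases or more, its highest correlation with another library was 0.889, below the lowest among the others, 0.926. Summed FPKM over these longer loci was still 24097700 in control replicate 1, against 942883 to 1258020 in the others. A cause at short loci that reaches past 300 bases is therefore not excluded by this cut. An air-dried leaf under a control label is also argued against: over 517 loci of 300 bases or more called without it and changed by at least 2-fold, its median position was -0.015 on a scale where the other controls lie at 0 and the air-dried samples at 1. Fewer fragments behind weakly expressed loci remains a candidate explanation, since 5.76% of loci of at least 1000 bases at 1 to 2 FPKM in the other libraries were listed under 0.01 FPKM in this one, against at most 0.608% in any other. Differences between the plants themselves were not tested.

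Falls of at least 4-fold at about 10 min are large for the time given. For the 42 such loci of 300 bases or more that were not listed at 0 in air-dried leaves, the median ratio of mean FPKM was 9.36 and the lowest 4.49; had synthesis stopped completely at the start of 10 min and RNA been taken at its end, half-lives of at most 3.10 min (median) and 4.61 min (the slowest) would be needed. The scaling between libraries is argued against, as the median log2 fold change over all tested loci was 0.0066. Short loci are also argued against, as 43 of the 44 falls were at loci of 300 bases or more. Of the 44, 37 were at such loci with a mean of at least 5 FPKM over both groups. Over tested loci of any span, 17202 of 22835 had such a mean. The control side largely sets this mean in a fall, and depth is unknown, so weak coverage in air-dried leaves is not excluded. Rapid RNA decay after drying is a hypothesis that these data leave untested. The labels do not say how long after drying the leaves were taken, and a difference in time of harvest or in handling between treated and control plants could also give such falls; neither was tested.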
